A study of Mus musculus with 4 samples.

How the data were processed

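RNA from 4 samples of sorted mouse retinal cells, labelled as ganglion cells, was analysed, 2 from mice given AAV2-CrAT and 2 from mice given AAV2-MCS. Group and replicate number were taken from the sample titles, which do not spell out MCS. Per the labels' protocols, total RNA was extracted with a Qiagen micro kit and cDNA was made with a low-input SMART-seq kit, which copies full-length polyadenylated transcripts from few cells and does not mark the strand, so reads of a gene and of its antisense partner cannot be told apart. The submitters' processing notes name STAR 2.7.2b and the builds GRCm38.p6 and mm10. The annotation release and the settings of the read counter are not given in the sources used here.

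The authors deposited a table of counts per gene and a table of FPKM values per gene for 56493 genes, with names, biotypes, exon lengths and ontology terms. Multiplying the deposited FPKM by exon length and by the column's total gave the estimated counts behind the deposited count table, which differed from the whole numbers there by at most 0.5. Between 43.6% and 44.9% of the values above 0 were not whole within 0.02, so the deposited counts were rounded from fractional values. How the fractions arose is not known here, and division of reads shared between places or genes is 1 way. The deposited values were therefore treated as rounded estimated counts. The design had assumed counts, and the same test applies. FPKM is per kilobase of summed exon length and scaled to the number of counted reads, computed by the authors before rounding. Coordinates in the tables carry no build name per the file headers. Of 51898 gene identifiers shared with a GRCm38 annotation, 1402 had the same start and end, so the tables use other coordinates than that build, and none were converted. The tables held 0 genes of the mitochondrial chromosome, so a fixed list of mitochondrially encoded transcripts was not analysed here. Each table also held 2 columns, 4 in all, of samples other than these, and they were not used in any step.

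Depth was 24494253 to 27097438 counts per library. The 10 most abundant genes took 6.63% to 7.99% of the counts, and protein-coding genes 95.3% to 95.8%. The 2 replicates of a group differed by more than the sampling noise of independent reads, with chi-square over degrees of freedom of 77.5 in CrAT and 131 in MCS. Amplified reads are not independent, which can raise this ratio by itself, so it does not tell biological from technical spread. Each library was counted as 1 sample.

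Genes were kept with edgeR's filterByExpr defaults by group, which left 19638, and libraries were scaled by TMM, with factors from 0.970 to 1.02. CPM values are TMM-scaled over the genes kept. The test was edgeR 4.0.16's quasi-likelihood F test (estimateDisp and glmQLFit with robust estimation, group as the only term, 2 residual degrees of freedom) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The common biological coefficient of variation was 0.404. Fold changes are CrAT over MCS. Of single values no exact permutation test was printed, since 2 libraries against 2 cannot give a two-sided p below 0.333. Before the data were examined, 43 gene lists of pathways and of cell types that a retinal sort could hold were fixed, of which 41 had at least 5 genes tested. They were tested with limma 3.58.1's camera on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, two-sided, adjusted over the lists. Camera with an estimated correlation and limma's fry were computed beside it. Of each list the members passing when adjusted over the list alone were counted.

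The genes named were set before the data were examined. They were Crat, 5 ganglion cell genes as checks of the sort (Rbpms, Slc17a6, Pou4f1, Thy1 and Sncg) and the 12 highest and 12 lowest genes past the threshold with an average of at least 1 log2 CPM and no overlap between the groups, leaving out predicted genes. As none passed, the 10 with the smallest p by the same conditions were named, and up to 4 members with the smallest p of each list described. Gnat1, Slc32a1, C1qa and Crym were chosen from the marker lists after their values were seen. Values of some genes that the rule takes are not reported here.

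The procedure was tested on simulated counts for 18947 genes with the means, library sizes and trended dispersion of these libraries for CrAT against MCS. Of 50 genes changed by each size, edgeR recovered 4% at 2-fold, 72% at 4-fold and 100% at 16-fold and at 64-fold, and 4 unchanged genes were called. A list of 30 genes shifted by 0.8 on the log2 scale was called and an unshifted one was not. The simulated genes were drawn independently of each other. This list result therefore does not tell how often camera calls unshifted lists of correlated genes, as in these libraries. Dispersion followed the average level of a gene, with no spread of its own per gene and no structure shared by replicate number. Recovery in these libraries may therefore be lower. H2-Aa and Gal, 7.15-fold and 14.9-fold higher in CrAT, did not pass in edgeR.

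The alternatives were DESeq2 size factors or library totals for scaling, no filter on low counts or at least 50 counts in 2 libraries, the replicate number as a block, each library left out in turn, a prior count of 0.5, DESeq2 1.42.0's Wald test, and limma with trend on log2(FPKM + 1) or log2(FPKM + 0.1) of the deposited FPKM for genes with FPKM of at least 1 in 2 libraries, or with no filter. DESeq2 gave an adjusted p for all but 11115 of 31851 genes with a count, and those stayed without one.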

Results

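Gene expression was measured by RNA sequencing in cells sorted from the mouse retina and labelled as retinal ganglion cells, the neurons whose axons form the optic nerve. Wild-type mice received an adeno-associated virus vector, AAV2, in the vitreous of the eye, and a month later the optic nerve was crushed, an injury of these axons that is followed by the death of many ganglion cells. Cells were then taken from the retina by fluorescence-activated cell sorting. The vector in 1 group of 2 libraries was AAV2-CrAT, for overexpression of carnitine acetyltransferase, and in the other group of 2 libraries it was AAV2-MCS. The comparison of the groups asks how expression in sorted cells of the injured retina differs when the vector carries CrAT. The deposited table held 24631411 and 26702852 counts for CrAT replicates 1 and 2, and 24494253 and 27097438 for MCS replicates 1 and 2. Between 25609 and 26869 genes had a count in a library, and the limit set by 3 counts lay between 0.109 and 0.126 CPM (counts scaled to the depth of the library). Floors of this kind cover counting error only, since amplified reads without molecular identifiers are not independent molecules. The labels do not say that the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

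Transcripts of Crat itself (ENSMUSG00000026853), which encodes carnitine O-acetyltransferase, an enzyme that moves acetyl groups between coenzyme A and carnitine, were 72.5 and 49.9 CPM in CrAT replicates 1 and 2, and 38.3 and 47.7 CPM in MCS replicates 1 and 2. The count table places the gene on chromosome 2, from 30290483 to 30305825 on the minus strand, with 5388 bases of summed exons. The raw counts were 1731 and 1324 against 953 and 1316. Both CrAT libraries lay above both MCS libraries, but the log2 fold change of 0.51 (SE 0.33), CrAT over MCS, was not larger than the spread between replicates (edgeR quasi-likelihood test, adjusted p = 1). Without CrAT replicate 1 it was 0.22. The labels give neither the species nor the sequence of the insert, so the part of it that this gene's count can hold is not known here. Ganglion cell transcripts were also few in these libraries, as given below. How much of the Crat count came from cells that the vector reached is not known either.

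Markers of several retinal cell types were present in all 4 sorted libraries. Rod transcripts were abundant, and Gnat1, the transducin subunit of rods, was at 10230 and 5301 CPM in the CrAT replicates and 9644 and 4421 CPM in the MCS replicates. The ganglion cell genes were much lower. Rbpms, an RNA-binding protein of ganglion cells, ranged from 2.75 to 8.58 CPM, the surface protein Thy1 from 10.98 to 30.1 CPM, gamma-synuclein (Sncg) from 2.74 to 26.4 CPM and the vesicular glutamate transporter Slc17a6 from 0.241 to 19.2 CPM. Pou4f1, a ganglion cell transcription factor, had 0 and 20 counts in the CrAT replicates and 1 and 15 in the MCS replicates, and the count of 0 allows up to 0.126 CPM. In both groups replicate 2 held more ganglion and amacrine cell transcripts in sum and fewer rod transcripts than replicate 1, with Rbpms in CrAT an exception. The summed level of 22 ganglion cell markers was 399.5 and 724.7 CPM in CrAT replicates 1 and 2 and 310.1 and 555 CPM in MCS replicates 1 and 2. Gad1, which makes the transmitter GABA in amacrine cells, was 75.3 and 690.9 CPM in CrAT and 33.9 and 260.3 CPM in MCS. Summed rod markers were 63120 and 34290 CPM in CrAT and 61690 and 37050 CPM in MCS. None of these marker lists differed between the groups by limma's camera test. The median log2 fold change was 0.37 for ganglion cell markers (adjusted p = 0.479), 0.23 for amacrine markers (adjusted p = 0.479) and 0.02 for rod markers (adjusted p = 0.969, with camera's direction and the mean, -0.01, on the other side of 0). The rod median was -0.42 without CrAT replicate 1 and -0.31 without MCS replicate 2. It was 0.44 without CrAT replicate 2 and 0.54 without MCS replicate 1. The ganglion cell and amacrine lists changed direction without CrAT replicate 2, to medians of -0.51 and -0.83, and without MCS replicate 1, to -0.064 and -0.032. Without CrAT replicate 1 or MCS replicate 2 both passed the threshold as higher in CrAT, with medians of 0.72 and 0.90 for ganglion cell and 1.00 and 1.73 for amacrine markers.

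**Figure D1:**
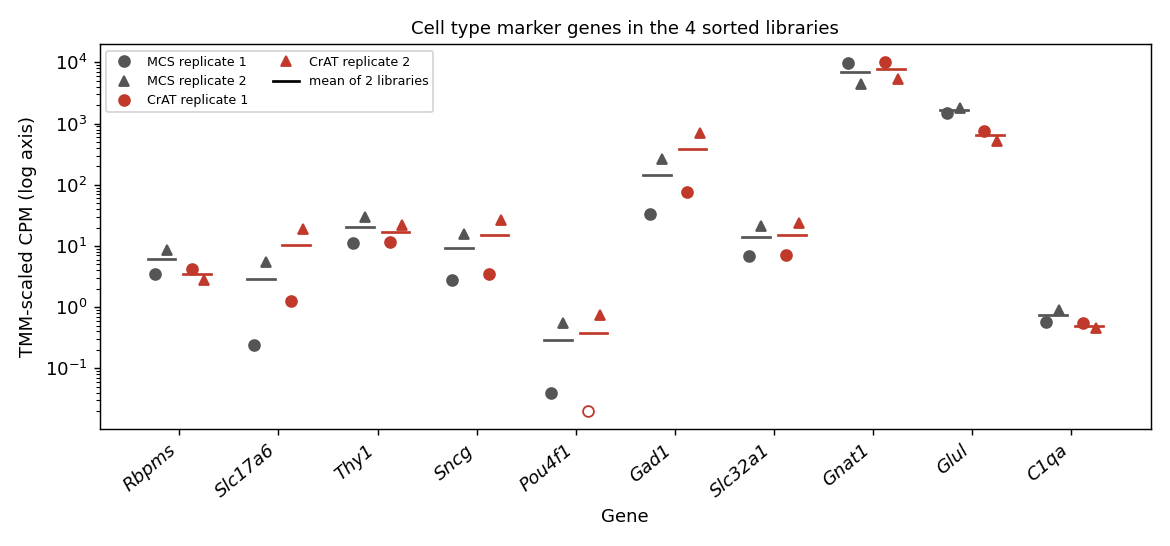
TMM-scaled CPM (log axis) of 10 cell type marker genes in the 4 libraries, with circles for replicate 1, triangles for replicate 2, and a line at the mean of each group of 2. Gnat1 lies between 4421 and 10230 CPM and Rbpms between 2.75 and 8.58 CPM, and the hollow circle is Pou4f1 in CrAT replicate 1, which had 0 counts and is drawn at 0.02 CPM.

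The groups parted most clearly in 3 gene lists fixed before the data were examined. Genes of major histocompatibility complex (MHC) class I antigen presentation and interferon response genes were higher in the CrAT libraries, and markers of Mueller glia, the main glial cell of the retina, were lower. All 20 antigen presentation genes had a positive log2 fold change, with a median of 1.07 (camera, adjusted p = 5.55e-15), as did all 30 interferon response genes, with a median of 0.77 (camera, adjusted p = 4.25e-12). Of 22 Mueller glia markers 21 were lower, with a median of -0.60 (camera, adjusted p = 4.11e-07). These p-values take a preset correlation of 0.01 between the genes of a list. With a correlation estimated from these libraries none of the calls held in camera. The adjusted p was 0.838 for antigen presentation, 0.576 for interferon response and 0.838 for the Mueller markers. The estimated correlation was 0.54 for antigen presentation and 0.70 for the Mueller markers, but -0.012 for interferon response, below the preset value. For interferon response the loss is therefore not due to correlation between its genes. With an estimated correlation camera also uses the 2 residual degrees of freedom, with which few lists can pass. The median of antigen presentation was 0.70 without CrAT replicate 2, and that of the Mueller markers was -0.33 without CrAT replicate 2 and -0.99 without CrAT replicate 1.

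No single gene differed between the groups at an adjusted p of 0.05 in edgeR. Of 19638 genes tested, 815 had an unadjusted p under 0.05, 251 higher and 564 lower in CrAT, where 982 are expected by chance. With the replicate number as a block 1922 did, also with no gene past the threshold. The count of 815 therefore does not show that the groups differ only as chance would. The 2 CrAT libraries lay on one side of both MCS libraries for 31.6% of genes, and chance gives 33.3%. DESeq2 called 49 genes, 31 higher and 18 lower, with 967 at an unadjusted p under 0.05. The 10 genes with the smallest p by edgeR among those chosen by a fixed rule all had an adjusted p of 1 there and passed 0.05 in DESeq2. The higher ones were H2-Q7, H2-Q6, Tap1, Psmb9, H2-Aa and Serpina3f. H2-Aa, the alpha chain of an MHC class II molecule, was 46.2 ± 12.7 CPM in CrAT and 6.47 ± 2.74 CPM in MCS (SD, n = 2 each), a log2 fold change of 2.84 (SE 0.46). Its adjusted p in DESeq2 was 2.21e-05. Serpina3f, a serine protease inhibitor, was 6.17 ± 0.497 CPM against 0.489 ± 0.333 CPM, a log2 fold change of 3.66 (SE 0.66). The lower ones were Col9a2, a collagen IX chain, with a log2 fold change of -2.15 (SE 0.36), the arrestin-domain gene Arrdc2 with -2.07 (SE 0.37), Prr5, a component of mTOR complex 2, with -1.87 (SE 0.33) and the sulfotransferase Chst2 with -1.71 (SE 0.31). Their adjusted p in DESeq2 was 0.00148, 0.00147, 0.00423 and 0.00865.

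Within the antigen presentation list, 17 of 20 genes had both CrAT libraries above both MCS libraries, and 9 passed when adjusted over the list alone, against 0 over all genes tested. Tap1, a subunit of the transporter that carries peptides into the endoplasmic reticulum, was 292 ± 73.1 CPM in CrAT and 79.5 ± 1.54 CPM in MCS (SD, n = 2 each), which is 3.67-fold. Psmb9, an inducible subunit of the immunoproteasome, was 125 ± 47.4 CPM against 28.2 ± 2.06 CPM, or 4.42-fold. The class I heavy chain genes H2-Q7 and H2-Q6 were 3.81-fold and 3.39-fold higher in CrAT. Their values are uncertain one by one, since the H2 genes have near-identical copies and the rule for reads shared between genes is not known here. The summed level of the list was 7530 and 9352 CPM in CrAT and 3687 and 3514 CPM in MCS. Of the interferon response genes, 24 of 30 had both CrAT libraries above both MCS libraries, and 3 passed when adjusted over the list alone, against 0 over all genes tested. The interferon regulatory factors Irf7 and Irf9 had log2 fold changes of 1.58 (SE 0.29) and 1.35 (SE 0.28). The interferon-induced GTPase Gbp2 had 1.29 (SE 0.34). Irf7 passed in DESeq2, with an adjusted p of 0.0122. The same libraries differed in the Mueller glia markers, and in Cd74, the invariant chain of MHC class II, which was 273.5 and 179.6 CPM in CrAT and 45.6 and 11.7 CPM in MCS (DESeq2, adjusted p = 0.000427).

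The Mueller glia markers summed to 20020 and 15900 CPM in CrAT and 29510 and 25560 CPM in MCS. In 16 of 22 both CrAT libraries lay below both MCS libraries. None passed when adjusted over the list alone or over all genes tested. Glul, the glutamine synthetase of Mueller cells, was 645 ± 173 CPM in CrAT and 1664 ± 237 CPM in MCS (SD, n = 2 each), a log2 fold change of -1.37 (SE 0.35). The transcription factor Sox9 had a log2 fold change of -1.34 (SE 0.40), the carbonic anhydrase Car14 of -1.17 (SE 0.31) and apolipoprotein E (Apoe) of -1.05 (SE 0.34). Crym was the only member not lower, at 0.01 (SE 0.36). Without CrAT replicate 2 the median of the list was -0.33 and the call was lost (camera, adjusted p = 0.109). Astrocyte markers had a median log2 fold change of -0.55, with 8 of 9 lower, and did not pass (camera, adjusted p = 0.051). These markers passed with library totals only (median -0.61, camera, adjusted p = 0.048) and had a median of -0.62 without MCS replicate 2. Among them Gfap, the intermediate filament of reactive glia, was 139 ± 27.7 CPM in CrAT and 231 ± 30.5 CPM in MCS (SD, n = 2 each). Microglia and macrophage markers had a median of -0.01 over 15 genes (camera, adjusted p = 0.930), with the mean of 0.03 and camera's direction positive. C1qa, a complement gene of microglia, had 12 to 25 counts in each library.

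**Figure D2:**
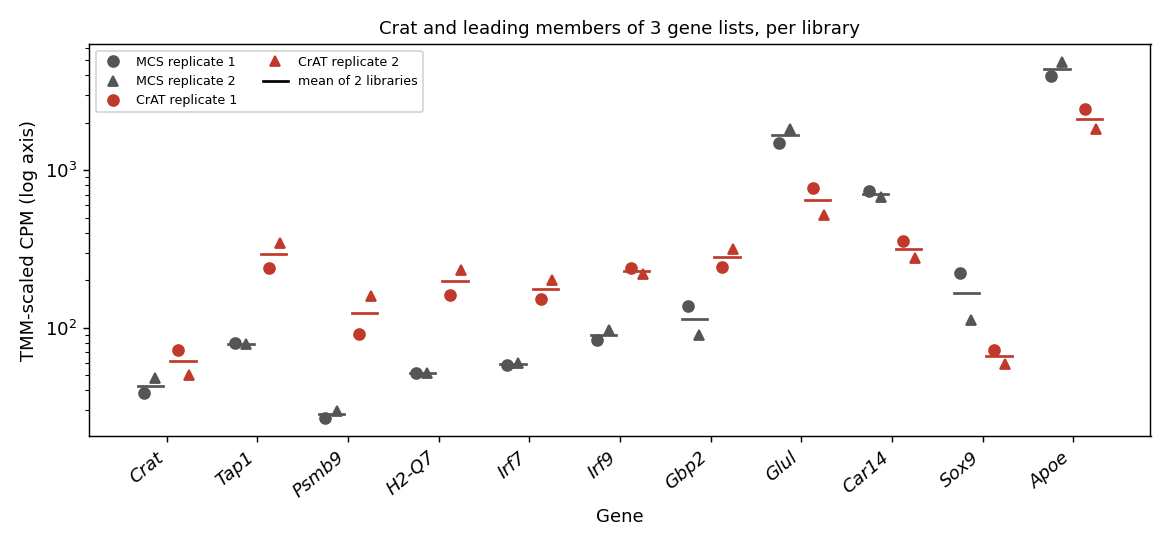
TMM-scaled CPM (log axis) of Crat and of 10 members of the antigen presentation, interferon response and Mueller glia lists in the 4 libraries, with circles for replicate 1, triangles for replicate 2 and a line at the mean of each group of 2. Tap1 is 240.3 and 343.8 CPM in CrAT and 80.5 and 78.4 CPM in MCS, while Glul is 767.4 and 522.3 CPM in CrAT and 1496 and 1831 CPM in MCS.

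Because carnitine acetyltransferase handles acetyl-CoA in mitochondria, lists of energy metabolism were compared as well. Nuclear-encoded subunits of oxidative phosphorylation were slightly higher in CrAT, with 53 of 58 above 0 and a median log2 fold change of 0.16 (camera, adjusted p = 0.00558). The adjusted p was 0.872 with an estimated correlation, and no member passed when adjusted over the list alone or over all genes tested. Sdha, the flavoprotein of succinate dehydrogenase, was 1023 ± 3.16 CPM in CrAT and 702 ± 23.3 CPM in MCS (SD, n = 2 each), a log2 fold change of 0.54 (SE 0.29). The complex I subunit Ndufs1 had 0.48 (SE 0.27). The call rested on MCS replicate 1. The summed level of the list there was 13120 CPM, against 20590 CPM in MCS replicate 2 and 18890 and 19960 CPM in CrAT replicates 1 and 2, and without MCS replicate 1 the median turned to -0.16 (camera, adjusted p = 0.324). The same library stood apart in nuclear retained RNA, with a summed level of 1501 CPM against 428.7 to 558.9 CPM in the other 3, and in cytosolic ribosomal protein transcripts, with 8768 CPM against 11460 to 13200 CPM. Without CrAT replicate 2 the call was also lost, at a median of 0.14 (camera, adjusted p = 0.178), and without MCS replicate 2 the median was 0.58.

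The other metabolic lists did not pass camera's test. In the tricarboxylic acid cycle 16 of 20 genes were higher, with a median log2 fold change of 0.27 (adjusted p = 0.051). Got1, the cytosolic aspartate aminotransferase, had 0.85 (SE 0.35) and Ogdh, of the 2-oxoglutarate dehydrogenase complex, 0.66 (SE 0.29), while the mitochondrial isocitrate dehydrogenase Idh2 had -0.77 (SE 0.27). Without MCS replicate 2 the list passed, at a median of 0.65 (adjusted p = 0.000552), and without MCS replicate 1 the median was 0.031 (adjusted p = 0.786). For genes of pyruvate dehydrogenase and acetyl-CoA supply the median was 0.22 and the mean -0.01 (adjusted p = 0.405). Without CrAT replicate 2 the median was 0.052 and camera's direction turned. Pdk1, a kinase that inhibits pyruvate dehydrogenase, had 0.93 (SE 0.34) and Pdha1, a subunit of the enzyme itself, 0.68 (SE 0.30). The carnitine shuttle and fatty acid oxidation list, the pathway nearest to carnitine acetyltransferase, had 14 genes higher and 15 lower, with a median of -0.11 (adjusted p = 0.479) that was 0.051 without MCS replicate 1. Its members with the smallest p were all lower. Acads, the short-chain acyl-CoA dehydrogenase, had a log2 fold change of -1.28 (SE 0.44), the thiolase Acaa2 -0.90 (SE 0.30), Hadh -0.75 (SE 0.28) and the long-chain dehydrogenase Acadl -0.70 (SE 0.30). All had an adjusted p of 1 in edgeR.

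Genes of the response to axon injury and of regeneration did not shift as groups. Summed ganglion cell markers were 310.1 to 724.7 CPM in these libraries, against 34290 to 63120 CPM for rod markers. A response of the ganglion cells alone could therefore be missed here. The axon injury list had a median log2 fold change of 0.22 (camera, adjusted p = 0.397), which was 0.028 without CrAT replicate 2 and 0.45 without MCS replicate 1. The regeneration list had a median of -0.10 with a mean of 0.27 (camera, adjusted p = 0.969). Its median was -0.24 without CrAT replicate 2 and 0.016 without MCS replicate 1, and camera's direction turned without MCS replicate 2. The transcription factor Jun, which axotomised ganglion cells induce, was 265 ± 26.1 CPM in CrAT and 551 ± 290 CPM in MCS (SD, n = 2 each). Both CrAT libraries lay below both MCS libraries, with a log2 fold change of -1.055 (SE 0.43). It did not pass over all genes tested in edgeR (adjusted p = 1). Much of the gap came from MCS replicate 1, at 756 CPM against 346.2 CPM in MCS replicate 2. Immediate early genes, a fixed list that holds Jun, stood apart in the same library. They summed to 5593 and 2964 CPM in MCS replicates 1 and 2, and 3408 and 2733 CPM in CrAT replicates 1 and 2. That list did not pass (camera, adjusted p = 0.104). Which cells the Jun transcripts came from was not tested. The neuropeptide galanin (Gal) had 53 and 868 counts in CrAT replicates 1 and 2 and 10 and 53 in the MCS replicates, and vasoactive intestinal peptide (Vip) had 21 and 313 against 0 and 3. Most of both came from CrAT replicate 2, the library with the highest Gad1. Gad1 differed far less, at 690.9 CPM in CrAT replicate 2 and 260.3 CPM in MCS replicate 2, against 32.7 and 1.92 CPM for Gal. Without CrAT replicate 2 the log2 fold change of Gal was 0.95, against 3.90 with it. Vip passed in DESeq2 (adjusted p = 0.000773). Targets of ATF4 in the integrated stress response had a median of -0.19 (camera, adjusted p = 0.175), and p53 targets and apoptosis genes had a median of -0.24 (camera, adjusted p = 0.120), which was -0.017 without MCS replicate 1 and -0.37 without CrAT replicate 1. Of these, asparagine synthetase (Asns) had a log2 fold change of 0.91 (SE 0.38), the p53 target Zmat3 -1.19 (SE 0.42) and the cell cycle inhibitor Cdkn1a -0.61 (SE 0.30), with an adjusted p of 1 each in edgeR. No list beyond the 4 named as past the threshold passed among the 41 tested.

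**Figure D3:**
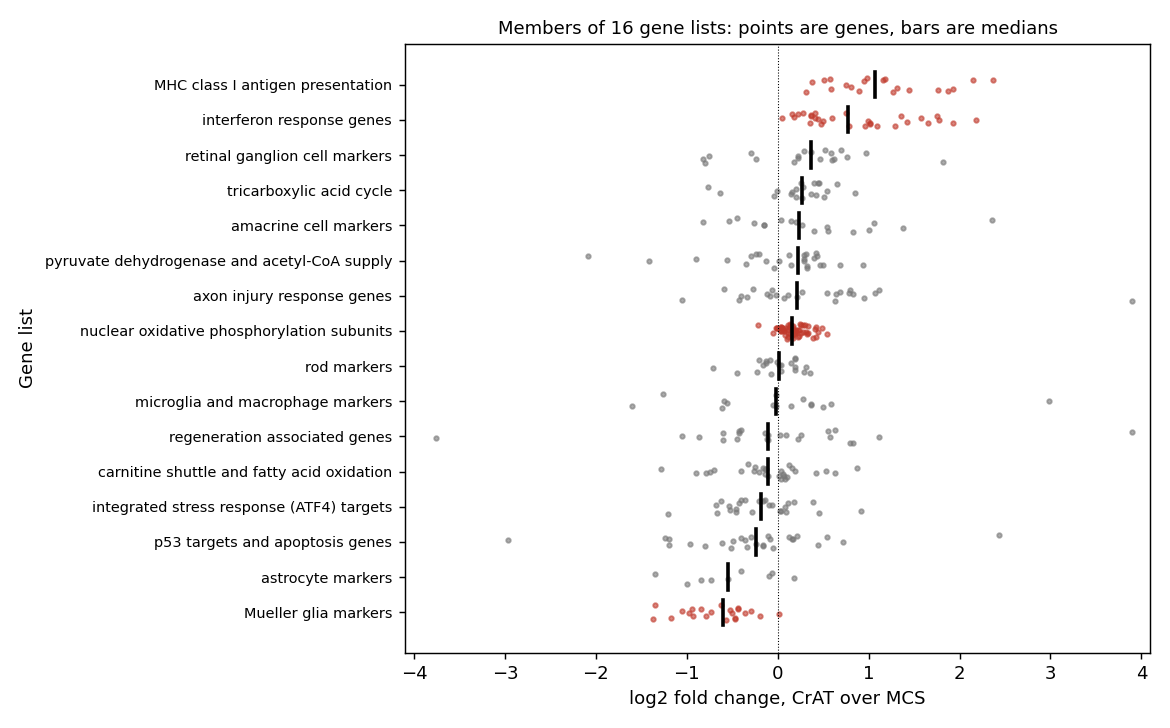
Log2 fold change, CrAT over MCS, of the members of 16 gene lists, 1 point per gene and a bar at the median of each list, with the 4 lists past an adjusted p of 0.05 in camera in red. Medians run from -0.60 for Mueller glia markers to 1.07 for antigen presentation, and 1 point beyond 4 in size is not drawn.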

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

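Alternatives with the H2 genes, Cd74 or broadly expressed markers left out of a list were chosen after seeing the data. No gene passed in edgeR under either other scaling, the stricter filter, the replicate block or any library left out, nor in limma on FPKM. Without a filter on low counts 2 passed (H2-Aa and Apol6, the second chosen after its values were seen, with 35 and 114 counts in CrAT and 0 in both MCS libraries), and DESeq2 called 49; the cause was not tested. Crat stayed above 0 and short of the threshold throughout, from 0.22 to 0.77 with a library left out. Of 73 named genes 63 kept their direction whichever library was left out. The exceptions ranged from -1.19 to 5.38 (Slc17a6), -1.38 to 2.45 (Sncg), -0.84 to 0.61 (Thy1), -5.92 to 3.09 (Pou4f1), -0.072 to 5.17 (Slc5a7), -0.18 to 1.86 (Slc6a5), -0.95 to 3.50 (Gad1), -0.81 to 0.038 (Nrl), -0.036 to 0.69 (Rcvrn) and -0.28 to 0.75 (Sag).

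Of pathway lists 3 passed, and 2 to 6 with a library left out, fewest without CrAT replicate 2 and most without MCS replicate 2; of cell type lists 1 passed, and 0 to 7, with 0 without CrAT replicate 2 and 7 without CrAT replicate 1. With library totals only, 3 cell type lists passed, Mueller glia, astrocyte (median -0.61) and red blood cell markers (2.59), and so did the tricarboxylic acid cycle (0.22), which also passed with the stricter filter (0.26). Rod markers passed as lower without CrAT replicate 1, and astrocyte markers without MCS replicate 2 (-0.62). With an estimated correlation 0 pathway and 0 cell type lists passed, and with fry 0 and 0; the smallest adjusted p of fry was 0.281 (interferon response). Antigen presentation and interferon response passed whichever library was left out, with medians from 0.70 (without CrAT replicate 2) to 1.36 (without CrAT replicate 1) and from 0.73 (without CrAT replicate 2) to 1.05 (without MCS replicate 1). Camera's direction turned, with medians, in the rod list without a filter (0.031) and under the block (0.0035), in the microglia list without a filter (-0.11) and without Cd74 (-0.016), and in the regeneration list with fry (-0.10). With a library left out it also turned in lists whose medians ranged from -0.16 to 0.58 (oxidative phosphorylation), 0.052 to 0.23 (acetyl-CoA supply), -0.51 to 0.90 (ganglion cell), -0.83 to 1.73 (amacrine), -0.42 to 0.54 (rod), -0.13 to 0.21 (microglia) and -0.24 to 0.016 (regeneration). Medians crossed 0 with camera's direction kept in the carnitine shuttle list without MCS replicate 1 (0.051), in the regeneration list without MCS replicate 1 (0.016), in the rod list with library totals only (-0.038), without CrAT replicate 1 (-0.42) and without MCS replicate 2 (-0.31), and in the microglia list with the stricter filter (0.27), without CrAT replicate 2 (0.099) and without MCS replicate 2 (0.21). The cause of these turns was not tested. With a library left out the medians of other lists ranged from 0.028 to 0.45 (axon injury), -0.37 to -0.017 (p53 targets), -0.87 to -0.40 (astrocyte), 0.031 to 0.65 (tricarboxylic acid cycle), -0.21 to 0.051 (carnitine shuttle), -0.27 to -0.21 (ATF4 targets) and -0.99 to -0.33 (Mueller glia). A lone library left in a group is assumed to vary like the other group.

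Same-numbered libraries deviated together from their group means (correlation 0.389 across genes), but the labels do not say that a number marks an animal or day. With the replicate number as a block, 0 genes passed in edgeR (smallest adjusted p 0.131). An unadjusted p under 0.05 was found for 1922 genes, against 815 without the block and 982 expected by chance. Under the block Crat was at 0.49, 3 pathway lists and 1 cell type list passed, and Pou4f1 turned to -0.022. The block changed no call, but more genes than chance gives then had a small unadjusted p.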

Other observations

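The tests on H2 copies, on the cell mixture between replicates and on genes of like length were chosen after the result was seen, as were the genes named in the first 2 paragraphs. The MHC class II genes H2-Eb1 and H2-Ab1 were 6.48-fold and 2.87-fold higher in CrAT, and their regulator Ciita, at 0.471 to 3.51 CPM, had a log2 fold change of 1.84 (SE 0.70). Of the immunity-related GTPases, which interferon induces, Igtp was at 505 ± 275 CPM in CrAT and 130 ± 19.9 CPM in MCS (SD, n = 2 each), Irgm1 at a log2 fold change of 1.58 (SE 0.33), Irgm2 at 1.89 (SE 0.37) and Iigp1 at 2.31 (SE 0.52). Among the genes lower in CrAT were the receptors Notch1 and Notch2, at -1.60 (SE 0.32) and -1.92 (SE 0.37), the laminin Lama5 at -1.88 (SE 0.37), the collagen Col2a1 at -1.65 (SE 0.37) and the vascular endothelial growth factor receptor Flt1 at -1.79 (SE 0.34). Each had an adjusted p of 1 in edgeR. All named here but H2-Ab1 and Ciita passed 0.05 in DESeq2.

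Among 1667 ontology terms of 15 to 300 genes, 95 passed camera's test at the preset correlation, 18 higher and 77 lower in CrAT, and 0 passed with an estimated correlation. The higher terms included the cellular response to interferon-beta (42 genes, median log2 fold change 1.06) and the response to type II interferon (23 genes, 0.70). The lower terms included canonical Wnt signalling (79 genes, -0.51), negative regulation of BMP signalling (45 genes, -0.55) and extracellular matrix organization (131 genes, -0.32). Of the 41 lists, red blood cell markers had the highest median log2 fold change, 2.63 over 7 genes, and did not pass (camera, adjusted p = 0.067). They passed with library totals only (2.59) and without CrAT replicate 1 (3.51). Hemoglobin transcripts stood out in 1 library, with Hba-a1 at 31.7 CPM in CrAT replicate 2 and 2.28 to 2.43 CPM in the other 3. Endothelial and pericyte markers did not pass as a list (median -0.29, camera, adjusted p = 0.120), with 4 genes higher and 8 lower. Without CrAT replicate 1 the median was -0.72. Flt1 was the 1 member that passed when adjusted over the list alone, at 51.0 to 243.7 CPM. Vwf was lower too, at 0 to 1.38 CPM. Pecam1, at 0.40 to 1.55 CPM, was higher in CrAT, with a log2 fold change of 1.39 (SE 0.71). Flt1 alone therefore does not show fewer vascular cells.

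By camera at the preset correlation, antigen presentation and interferon genes were higher in CrAT. With an estimated correlation neither list passed (camera, adjusted p = 0.838 and 0.576). Both CrAT libraries lay above both MCS libraries in 17 of 20 and 24 of 30 genes. No single gene passed over all genes tested in edgeR. Shared reads between H2 copies do not account for the rise in the members that are not H2 genes. Those 12 had a median log2 fold change of 0.78, against 1.07 for the whole list. How far shared reads bear on the H2 genes themselves was not tested. The summed level of 12 transcripts common to leukocytes was 40.3 and 58.7 CPM in CrAT and 31.5 and 58.7 CPM in MCS, a log2 ratio of 0.13. This sum rose from replicate 1 to replicate 2 in both groups, while Cd74 fell in both. Ptprc, a leukocyte gene chosen after its values were seen, had 1 and 3 counts in CrAT replicates 1 and 2 and 8 and 2 in MCS replicates 1 and 2. The sum may thus hold transcripts of other retinal cells, which makes it a weak test. It gives no sign of more leukocytes in CrAT, but cannot exclude a small number of them. A mixture that follows the replicate number alone is balanced here, since each group held replicate 1 and replicate 2. Replicate 2 over replicate 1 gave a median log2 ratio of the antigen presentation list of -0.056 in MCS, against 0.52 in CrAT. These ratios cannot tell whether the mixture differed between the groups. The 4 libraries allow 3 splits into pairs, too few for a share under 0.05, and the real median was 1.07 against 0.38 for the highest other in size. An interferon response that goes with the CrAT vector, by its insert, dose or preparation, may be followed up, and these data cannot separate those. Differences between the groups in animals, handling or cell mixture would also go with the vector here, and were not tested.

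By camera at the preset correlation, Mueller glia markers were lower in CrAT. With an estimated correlation the list did not pass (camera, adjusted p = 0.838), and without CrAT replicate 2 its median was -0.33. In 16 of 22 markers both CrAT libraries lay below both MCS libraries. A trend with gene length is argued against, since the 100 genes nearest in exon length to each marker had a median log2 fold change between -0.071 and 0.11 (0.053 over the markers), against -0.60 for the list. Removal of a fitted length trend was no test, as it moved genes by a median of 0.0178. Fewer Mueller cells in the CrAT sorts may account for the lower markers. Of 16 narrower markers, left after the broadly expressed members were taken out, 15 were lower, which restates the pattern. Taking those members out moved the median from -0.60 to -0.79, and 6.25% (Crym alone) lay over 2 standard errors from the latter. Standard errors of 0.29 to 0.58 make this a coarse test, which markers lowered by unlike amounts could also pass. Lower expression per Mueller cell stays open and was not tested. The 3 splits of the libraries are too few for a share under 0.05, with -0.60 for the real one and 0.37 for the highest other in size.

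Split by replicate number in place of vector, the libraries gave 832 calls in DESeq2, against 49 for the real split and 0 for the crossed one, and 0 in edgeR for each of the 3 splits. Camera at the preset correlation passed 9 lists by replicate number and 4 for the crossed split, as many as the 4 for the real one, so a list past the threshold does not by itself mark the vector. Oxidative phosphorylation passed in both of the other splits and the Mueller markers by replicate number (adjusted p = 0.010), while antigen presentation and interferon response passed in neither, with adjusted p of 0.649 and 0.881 by number and 0.0934 and 0.680 crossed. The 832 calls point to a structure of the samples that follows the replicate number, in which amacrine, ganglion cell and rod transcripts differ within both groups.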
